A study of Arabidopsis thaliana with 15 samples.

How the data were processed

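RNA was measured in rosette leaves of Arabidopsis thaliana, accession Columbia, in 5 genotypes with 3 biological replicates each, 15 arrays in all: wild type, nhx5-2, nhx6-2, nhx5-2/nhx6-2 and nhx5-1/nhx6-1. Plants were 4 weeks old and grew on soil in 8 h light and 16 h dark, per the labels' protocols. The nhx5-2 allele is a GABI T-DNA line and nhx6-2 a SALK line, and the second double knockout combines a WiscDsLox insertion in NHX5 with another SALK insertion in NHX6. Total RNA was isolated with Qiagen columns, and biotin-labelled RNA was made from 6 µg and hybridized to the Affymetrix Arabidopsis genome array, per the labels' protocols.

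The authors deposited 1 table with a score per probe set and array, in a log-like unit with a mean near 0 on each array. The background correction, summarization, normalization and log base behind this score are not given in the sources used here. The plan, written before the values were seen, assumed linear or log2 intensities. The deposited score was used as it stands, without a further transformation, and differences are in deposited units. To give these units a size, the deposited score of the bacterial and phage hybridization spike-ins was regressed on the log2 of their nominal concentrations of 1.5, 5, 25 and 100 pM, on 9 probe sets per array. These concentrations are the array maker's nominal values and were assumed here. The slope was 0.681 units per doubling, with an SD of 0.0281 over the 15 arrays, and fold values in the text divide the difference by this slope. As the slope comes from bright spike-ins, it need not hold for dim transcripts.

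The table had 22810 probe sets. The 64 control probe sets were left out of the tests, leaving 22746, and served only for quality: the 3′ minus 5′ signal is the mean over actin and GAPDH of the difference between their 3′ and 5′ control probe sets. Probe sets were named from the annotation table given with the files, in which 13513 had 1 gene (13355 different genes), 503 had several and 8730 were not listed. Of the 13513, 13436 matched the reference gene table of assembly TAIR10.1, which gave names and neighbours only. NHX5 and NHX6 had no listed probe set, so their transcripts are not analysed here. No probe set was removed for low signal in the main analysis.

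A linear model with 1 mean per genotype was fitted to all 15 arrays for each probe set with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings), and p values were adjusted over the 22746 probe sets by the Benjamini-Hochberg method, with a threshold of 0.05. Standard errors are those of the model with the moderated spread. The comparisons were each knockout against wild type, the mean of both double knockouts against wild type, nhx5-1/nhx6-1 against nhx5-2/nhx6-2, nhx5-2/nhx6-2 against each single knockout, and the non-additive effect, which is nhx5-2/nhx6-2 minus nhx5-2 minus nhx6-2 plus wild type. A probe set changed in both double knockouts when it passed in each with the same sign. The words rose, fell and changed are used for probe sets that passed. Beside the test, the share of probe sets for which all 3 values of a genotype lay on one side of all 3 values of the other was counted, 10% being the share by chance. Each group had 3 arrays, and an exact test of 3 against 3 cannot go below 0.1.

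Genes were named by a rule fixed before the values were seen. Among probe sets with exactly 1 gene, past the threshold and with no overlap between the compared arrays, the 10 largest rises and 10 largest falls were named for each double knockout and for both together (ranked there by the smaller difference), and the 5 largest each way for each single knockout, the non-additive effect and the difference between the double knockouts. The no-overlap rule used the arrays of both double knockouts for their difference, and those of nhx5-2/nhx6-2 and wild type for the non-additive effect. From each list up to 4 members with the smallest p were named.

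Gene lists were fixed before the values were seen: cation antiporters, potassium and sodium transport, proton pumps, endosomal and vacuolar trafficking, vacuolar proteases, folding in the endoplasmic reticulum, autophagy, abscisic acid, drought and cold, salicylic acid, jasmonate, touch and wounding, auxin, cell cycle, cell wall loosening, photosynthesis, clock, anthocyanin, senescence, glucosinolates, iron, phosphate, heat shock, flower, shoot meristem, guard cells, vascular tissue, trichomes and root. Chloroplast-encoded and mitochondrion-encoded genes were planned as lists by gene identifier. The chloroplast list was instead taken from the chromosome in the reference gene table. The mitochondrial list was taken from gene names beginning with nad, cox, ccb and the like, among probe sets without a match in that table. A further 12 lists were formed from gene name families after the results were seen and are reported only among the other observations. A gene is called measured where the annotation assigned a probe set to it alone. Others may lie among the 8730 probe sets not listed. Where a gene had several probe sets, the one with the highest mean was used. Lists with at least 3 measured members were tested in all 9 comparisons with limma's camera, with a preset correlation of 0.01 between genes and again with a correlation estimated for each list, and adjusted over 26 lists within a comparison. For each list the members past the threshold are counted, and once more with p adjusted over the list alone.

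Overlaps between comparisons that share the wild type arrays were set against the overlap of independent lists of the same sizes. They were also set against 20 simulations of unchanged groups. Every array in these, wild type included, was drawn as independent noise with the spread of each probe set. The comparisons shared the simulated wild type arrays. The code was tested on simulated values for the 22746 probe sets with the observed means and spreads and 200 changed probe sets. Differences of 0.3 units were recovered in 41.7% to 52.5% of cases, those of 0.6 in 89.4% to 100% and those of 1 in 96.9% to 100%, with 6 to 14 false calls among 164 to 175 per comparison. Changes well below 0.3 units were therefore mostly out of reach.

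The alternatives were quantile normalization, arrays shifted to the same median, the dimmest 25% of probe sets left out, only the arrays of the groups compared, the replicate number in the model, a variance prior with trend and robust estimation, array weights (limma's gene by gene method, since the default did not converge), each array left out in turn, only probe sets with 1 gene, a difference of at least 1 unit beside the threshold, and, for lists, the mean of all probe sets of a gene and the estimated correlation. Added after the values were seen were the omission of both arrays with a low SD and covariates for the cre spike-in and for the 3′ minus 5′ signal. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.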

Results

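Transcripts were measured in rosette leaves of 4 week old Arabidopsis thaliana plants, accession Columbia, grown on soil in days of 8 h light and 16 h dark. The Affymetrix Arabidopsis genome array was used, with 1 array per sample and 15 arrays in all. There were 5 genotypes with 3 biological replicates each: wild type, the single knockouts nhx5-2 and nhx6-2, and 2 double knockout lines. One double knockout, nhx5-2/nhx6-2, carried the alleles of both single knockouts, and the other, nhx5-1/nhx6-1, carried a different insertion in each gene. NHX5 and NHX6 code for antiporters of the endosomal membranes that exchange sodium or potassium ions for protons. The comparisons asked how the leaf transcriptome changed when 1 or both antiporters were lost, and which changes both pairs of alleles had in common.

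Each array gave 22810 values on a log-like scale whose base is not given in the sources used here, of which 22746 probe sets entered the tests and 64 control probe sets did not. Differences are therefore given in deposited units. As a yardstick, the hybridization spike-ins rose by 0.681 units per doubling of their nominal concentration (SD 0.0281 over the 15 arrays), so that 1 unit stood for about 2.77-fold on that scale, and fold values below rest on it. Errors of differences are standard errors of the limma model, with 3 arrays per genotype, and the number of arrays limits their precision. The median array value lay between −0.32 and −0.22. Arrays of the same genotype correlated at r = 0.957 to 0.997 across probe sets, and arrays of different genotypes at 0.940 to 0.996. The first principal component held 37.7% of the variance, with the 6 double knockout arrays between 11.4 and 19.6 and the other 9 arrays between −16.3 and 0.32. The second held 19.5%, and its highest values belonged to nhx5-1/nhx6-1 replicate 3 (27.3) and nhx5-2 replicate 1 (14.8), whose values also had the lowest SD, 0.762 and 0.797, against 0.876 to 0.893 on the others.

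The targeted genes could not be checked, because no probe set was listed for NHX5 or NHX6 in the annotation used here. The genotypes therefore rest on the labels.

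RNA quality differed between the genotypes. The signal of the 3′ minus the 5′ control probe sets of actin and GAPDH, which rises as RNA is degraded or incompletely transcribed, was 1.86 ± 0.10 units in wild type (SD, n = 3), 1.51 ± 0.06 in nhx5-2 and 1.61 ± 0.07 in nhx6-2. It was 1.98 ± 0.20 in nhx5-2/nhx6-2 and 2.34 ± 0.06 in nhx5-1/nhx6-1, whose arrays, all at 2.27 or more, lay above every wild type array, at 1.79 to 1.97.

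**Figure D1:**
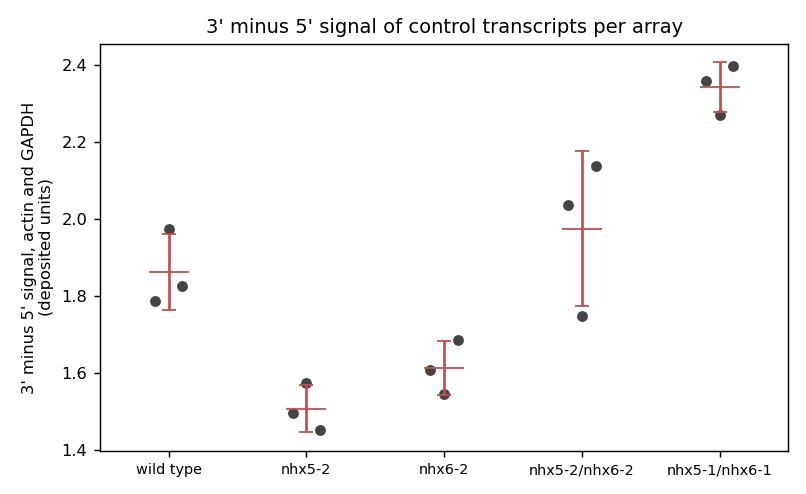
The 3′ minus 5′ signal of the actin and GAPDH control probe sets, in deposited units, on each of the 15 arrays by genotype, with the mean and SD of each genotype (n = 3). The nhx5-1/nhx6-1 arrays lie at 2.27 or more, above the wild type arrays at 1.79 to 1.97, and both single knockouts lie below wild type.

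In the nhx5-2/nhx6-2 double knockout the acid phosphatase-like gene AT5G44020 lay at −2.43 ± 0.16 units from wild type (SE, n = 3), about 11.8-fold lower. AT1G04040, also acid phosphatase-like, lay at −1.89 ± 0.13 units, about 6.88-fold lower. AT2G32500, which codes for a protein with a stress responsive A/B barrel domain, differed by −2.10 ± 0.09, a lower bound of its fall since its values lay at the no-target level, the median of control probe sets without a target on the arrays. AT3G16670, from the Ole e 1 and extensin family of secreted proteins, differed by −1.79 ± 0.16 and the pectin methylesterase inhibitor family gene AT1G23205 by −1.57 ± 0.15. Among genes that rose, CCL was higher by 2.04 ± 0.15 units, about 7.97-fold, and the stress-induced ubiquitin ligase gene PUB19 by 1.77 ± 0.33.

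Further falls in nhx5-2/nhx6-2 were measured for AT5G48490, a lipid transfer protein gene (−1.33 ± 0.20), AT3G09440, a cytosolic heat shock cognate chaperone gene (−1.31 ± 0.11), AT1G29660, a GDSL lipase gene (−1.29 ± 0.14), AT5G03120 (−1.26 ± 0.13) and AT4G16980 (−1.25 ± 0.16). A second probe set of AT4G16980 differed by −0.17 and did not pass the test. The other leading rises were AT1G76960 (1.83 ± 0.24), AT2G37870 (1.75 ± 0.20), ALDH7B4, an aldehyde dehydrogenase gene induced by drought and salt (1.42 ± 0.30), COR15A, a cold-regulated gene of the chloroplast stroma (1.42 ± 0.33), AT1G62510 (1.42 ± 0.17), the amino acid transporter family gene AT2G41190 (1.39 ± 0.28), AT3G53980 (1.35 ± 0.17) and the malate transporter family gene AT1G68600 (1.31 ± 0.19). AT2G37870, AT1G62510 and AT3G53980 belong to the lipid transfer and seed storage protein family. Some of these genes were also high on nhx6-2 replicate 3, unlike on nhx6-2 replicates 1 and 2. ALDH7B4 stood at 2.24 there against 0.88 and 0.76, COR15A at 3.45 against 1.85 and 1.90, and PUB19 at 1.13 against −0.24 and −0.30. CCL and AT3G53980 did not stand apart on that array.

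Of 11 measured autophagy genes, 7 rose in nhx5-2/nhx6-2, none fell and 4 did not pass the test, and 9 rose when p was adjusted over the list alone. ATG8F (0.62 ± 0.12), ATG8C (0.56 ± 0.09), APG8A (0.56 ± 0.08) and ATG8G (0.37 ± 0.05), which code for the ubiquitin-like proteins of the autophagosome membrane, were among them. The camera test of the list, with a median difference of 0.32, gave an adjusted p of 6.04e-09 with the preset correlation and an adjusted p = 0.196 with an estimated correlation. Of 5 measured vacuolar proteases, 3 rose and 2 did not pass the test, and 3 rose when adjusted over the list alone: GAMMA-VPE (0.83 ± 0.14) and BETA-VPE (0.61 ± 0.12), which process vacuolar proteins, and the aspartic protease gene APA1 (0.44 ± 0.11). On wild type replicate 2 GAMMA-VPE stood at 1.71 against 1.28 and 1.25 on replicates 1 and 3, and APA1 was lower there, at 2.76 against 2.96 and 2.92. The list test gave an adjusted p of 0.00544, and an adjusted p = 0.196 with an estimated correlation. The proteases that did not pass, ALPHA-VPE and DELTA-VPE, lay within the range of the no-target medians over all arrays in wild type and nhx5-2/nhx6-2, so little can be read from them. Of 5 measured genes of protein folding in the endoplasmic reticulum, 2 rose and 3 did not pass the test, and 3 rose when adjusted over the list alone. The 2 were ATERDJ3B (0.61 ± 0.13) and the calnexin gene AT5G07340 (0.42 ± 0.08), and the list gave an adjusted p of 0.00331, and an adjusted p = 0.203 with an estimated correlation. Of 4 measured genes of the abscisic acid, drought and cold response, COR15A rose and 3 did not pass the test, and 3 rose when adjusted over the list alone. The list median was 0.70, with an adjusted p of 0.00544, and an adjusted p = 0.512 with an estimated correlation.

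In all, 2232 probe sets changed in nhx5-2/nhx6-2 (9.81% of those tested), 972 higher and 1260 lower, of which 1156 had 1 gene. A difference of at least 1 unit was reached by 120 of them, and the median size was 0.39 units. Without wild type replicate 2 the split was 1057 higher and 1033 lower. The 3 mutant and 3 wild type arrays did not overlap for 34.0% of probe sets, against 10% by chance. The count was 1245 without wild type replicate 1, 1165 without wild type replicate 3, and 1218 and 1439 without nhx5-2/nhx6-2 replicates 1 and 2. Calls that ended without 1 array were COR15A (adjusted p 0.0575, 0.0758 and 0.0629 without wild type replicates 1 and 3 and mutant replicate 1), APA1 (0.064 without wild type replicate 2, and 0.0611, 0.052 and 0.053 without mutant replicates 1, 2 and 3) and ATERDJ3B (0.0557 and 0.0544 without mutant replicates 1 and 2).

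In the nhx5-1/nhx6-1 double knockout the same pair of acid phosphatase-like genes led the falls, AT5G44020 at −2.18 ± 0.16 units from wild type (SE, n = 3), about 9.18-fold lower, and AT1G04040 at −1.86 ± 0.13. AT3G16670 differed by −1.86 ± 0.16, AT1G23205 by −1.42 ± 0.15, the methionine sulfoxide reductase gene MSRB6 by −1.402 ± 0.23, and CHIL, a chalcone isomerase-like gene of flavonoid synthesis, by −1.21 ± 0.12. CCL was higher by 1.69 ± 0.15 units, the EF-hand calcium-binding protein gene AT2G46600 by 1.49 ± 0.20, AT2G15960 by 1.45 ± 0.14 and PUB19 by 1.395 ± 0.33.

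AT1G29660 (−1.38 ± 0.14), AT4G16980 (−1.35 ± 0.16, with −0.01 at its second probe set), AT3G56290 (−1.18 ± 0.11) and the glutaredoxin gene AT1G06830 (−1.15 ± 0.08) also fell. Further rises were AT1G27030 (1.403 ± 0.12), the lectin family gene AT1G52000 (1.39 ± 0.38), AT4G01390 (1.38 ± 0.09), the universal stress protein family gene AT3G62550 (1.35 ± 0.15), AT3G05640, a type 2C protein phosphatase gene (1.33 ± 0.14), and AT1G76960 (1.33 ± 0.24).

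Of 11 autophagy genes, 6 rose in nhx5-1/nhx6-1 and 5 did not pass the test, and 8 rose when adjusted over the list alone, among them ATG8C (0.58 ± 0.09), APG8A (0.40 ± 0.08), ATG8G (0.38 ± 0.05) and ATG8D (0.35 ± 0.07). The list gave an adjusted p of 3.55e-05, and an adjusted p = 0.356 with an estimated correlation. Of the 4 abscisic acid, drought and cold genes, the dehydrin gene COR47 (1.03 ± 0.25) and COR15B (0.87 ± 0.20) rose and the other 2 did not pass the test, with 3 higher when adjusted over the list alone. That list gave an adjusted p of 0.0166, and an adjusted p = 0.512 with an estimated correlation. Wild type replicate 2, high for ATG8C, APG8A and GAMMA-VPE as given above, also stood at 1.64 for COR15B, against 0.96 and 0.95 on wild type replicates 1 and 3. Without nhx5-1/nhx6-1 replicate 2 the adjusted p of this list was 0.0944. Of 5 vacuolar proteases, BETA-VPE (0.68 ± 0.12) and GAMMA-VPE (0.63 ± 0.14) rose, also when adjusted over the list alone, but the list as a whole did not pass (adjusted p 0.0553, and 0.0453 without nhx5-1/nhx6-1 replicate 3). None of the 5 folding genes passed, 2 did when adjusted over the list alone, and the list test gave an adjusted p of 0.116.

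Of 69 chloroplast-encoded genes 8 rose in nhx5-1/nhx6-1, which also had the highest 3′ minus 5′ signal, none fell and 61 did not pass, with 9 higher when adjusted over the list alone. The transcript of psbA, for a photosystem II core protein, was higher by 1.02 ± 0.19 units. The list had a median of 0.28 and an adjusted p of 3.55e-05, an adjusted p = 0.730 with an estimated correlation, and a median of 0.0334 (adjusted p 0.535) without wild type replicate 2. Of 16 mitochondrion-encoded genes 6 rose and 10 did not pass, with 7 higher when adjusted over the list alone, among them nad9 (0.37 ± 0.05), ccb452 (0.39 ± 0.05) and nad4 (0.59 ± 0.11). The mitochondrial list gave an adjusted p of 0.000163, and an adjusted p = 0.356 with an estimated correlation. Of 8 nuclear photosynthesis genes, LHCB4.3, a light-harvesting antenna gene, fell (−0.89 ± 0.13) and 7 did not pass, also when adjusted over the list alone. This list had a median of −0.29 and an adjusted p of 0.0166, and an adjusted p = 0.512 with an estimated correlation.

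In all, 2736 probe sets changed in nhx5-1/nhx6-1 (12.03%), 1166 higher and 1570 lower, 1409 of them with 1 gene and 95 by at least 1 unit, and the genotypes did not overlap for 26.3% of probe sets against 10% by chance. With every array shifted to the same median the split was 629 higher and 1994 lower. It turned to 1662 higher and 1210 lower without nhx5-1/nhx6-1 replicate 3, and to 2190 and 1653 without both arrays of low SD, that one and nhx5-2 replicate 1. The count was 1479 and 1499 without wild type replicates 1 and 3, and 24 with the 3′ minus 5′ signal as a covariate, where the median difference of the 2736 probe sets went from 0.36 to 0.31 units and its standard error from 0.08 to 0.15. Without single arrays the calls of PUB19 (adjusted p 0.051, 0.0585 and 0.0538 without wild type replicates 1 and 3 and mutant replicate 2), COR47 (0.0634, 0.0743 and 0.0613 without the same arrays), COR15B (0.065 and 0.0638 without wild type replicates 1 and 3), GAMMA-VPE (0.0633 and 0.0639 likewise) and AT1G52000 (0.121, 0.0939, 0.0757 and 0.101 without wild type replicates 1 and 3 and mutant replicates 1 and 2) ended. The photosynthesis list had an adjusted p of 0.0796, 0.0668, 0.0876 and 0.0928 without wild type replicates 1 and 3 and mutant replicates 2 and 3.

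**Figure D2:**
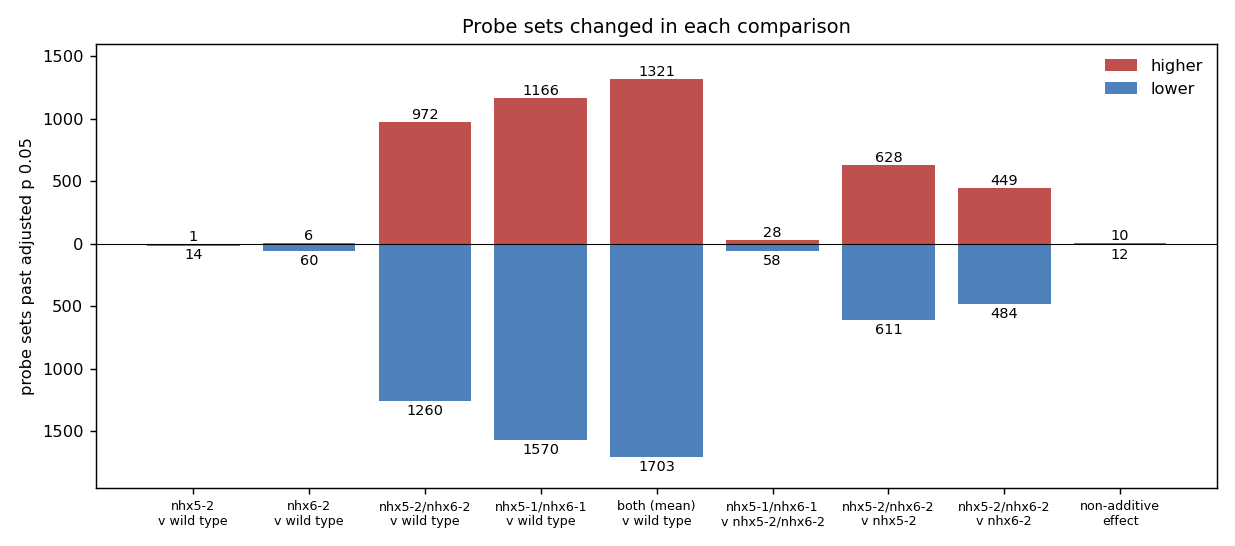
Number of probe sets higher (upper bars) and lower (lower bars) at an adjusted p of 0.05 in each of 9 comparisons, from 22746 tested. The bars of both double knockouts against wild type, with 2232 and 2736 probe sets, stand far above those of the single knockouts, with 15 and 66.

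Both double knockouts shared most of their strongest changes. Besides AT5G44020, AT1G04040, AT3G16670, AT1G23205, AT1G29660 and AT4G16980, the genes with the largest falls in both were AT3G09440 (−1.31 and −1.11 ± 0.11 in nhx5-2/nhx6-2 and nhx5-1/nhx6-1), CHIL (−1.11 and −1.21 ± 0.12), MSRB6 (−1.07 and −1.402 ± 0.23) and AT1G06830 (−1.06 and −1.15 ± 0.08). The largest shared rises were CCL, PUB19, AT1G76960, AT3G62550 (1.29 and 1.35 ± 0.15), AT1G68600 (1.31 and 1.28 ± 0.19), ALDH7B4 (1.42 and 1.24 ± 0.30), AT3G05640 (1.18 and 1.33 ± 0.14), AT2G15960 (1.17 and 1.45 ± 0.14), AT1G62510 (1.42 and 1.14 ± 0.17) and the lipase family gene AT1G73480 (1.08 and 1.05 ± 0.20). For the named autophagy genes APG8A, ATG8C, ATG8F, ATG8G and ATG8D and for GAMMA-VPE and BETA-VPE the call also held in both lines.

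In total 1467 probe sets changed the same way in both lines, 524 higher and 943 lower, and 3 in opposite directions. The split was 826 and 944 without nhx5-1/nhx6-1 replicate 3, 1071 and 1191 without both arrays of low SD, 211 and 556 without wild type replicate 3, and 342 and 898 with the arrays shifted to one median. Of the 1467, 742 had 1 gene. Independent lists of these sizes would share 49.8 higher and 87.0 lower. Unchanged groups set against shared simulated wild type arrays had 0 in common in 20 simulations. With no true change hardly any probe set is called, so this 0 does not measure what the shared controls add. Across probe sets, which are not independent replicates, the differences of the lines correlated at r = 0.79 against 0.50 simulated, with a covariance of 0.0329 against 0.00372. Of the probe sets called in nhx5-2/nhx6-2, 97.4% had the same sign in nhx5-1/nhx6-1. The simulated share, 66.8%, was taken over all probe sets and not over called ones, so the 2 shares cannot be compared directly. With only 3 arrays the wild type could not be split into parts of 2, so part of the excess may come from the shared controls. The shared count was 796 and 767 without wild type replicates 1 and 3, 940 without nhx5-2/nhx6-2 replicate 1, and 21 with the 3′ minus 5′ covariate. MSRB6 in nhx5-2/nhx6-2 had an adjusted p of 0.0536 without mutant replicate 1, and ALDH7B4 in nhx5-1/nhx6-1 one of 0.065, 0.0604 and 0.0585 without wild type replicates 1 and 3 and mutant replicate 2.

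**Figure D3:**
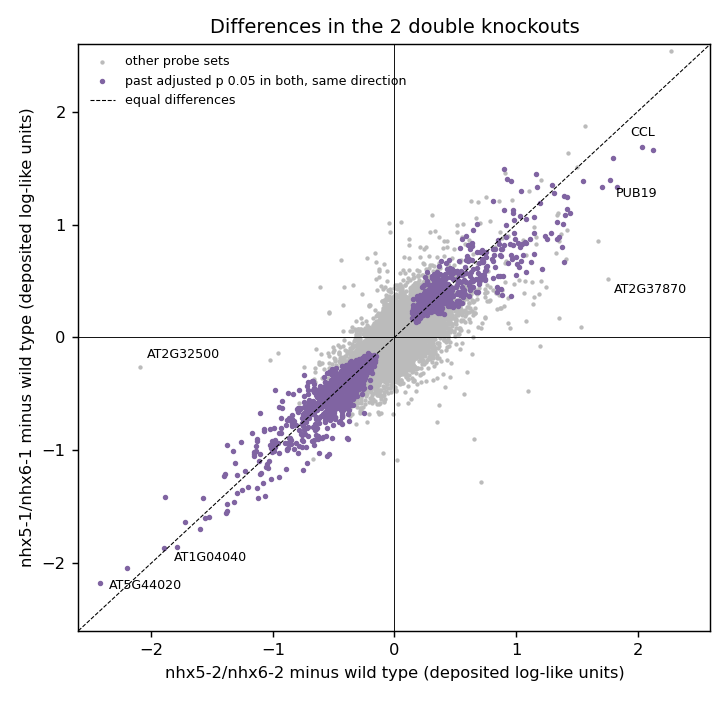
Difference from wild type in nhx5-1/nhx6-1 against that in nhx5-2/nhx6-2 for each tested probe set, in deposited units, with the 1467 probe sets that changed the same way in both lines in purple and equal differences on the dashed line. The points follow the dashed line, with r = 0.79 across probe sets.

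For the mean of both double knockouts, 8 of 11 autophagy genes rose and 3 did not pass, 3 of 5 vacuolar proteases, 2 of 5 folding genes and 3 of 4 abscisic acid, drought and cold genes rose, and 5 of 16 mitochondrion-encoded genes did, with the rest of each list not past the threshold. Adjusted over the list alone, 8, 3, 2, 3 and 6 rose. These 5 lists passed the camera test, with adjusted p of 1.96e-07, 0.0123, 0.0123, 0.00793 and 0.00321 in that order, and no fixed list had an adjusted p under 0.312 with an estimated correlation. In total 3024 probe sets changed, 1321 higher and 1703 lower. Shifting the arrays to one median gave 867 higher and 1766 lower, while the majority turned without nhx5-1/nhx6-1 replicate 3 (1981 and 1784) and without both arrays of low SD (2428 and 2206). The count was 1661 and 1596 without wild type replicates 1 and 3 and 429 with the 3′ minus 5′ covariate.

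In the nhx5-2 single knockout AT2G32500 fell by far the most, at −2.04 ± 0.09 units from wild type (SE, n = 3; adjusted p 7.44e-08). Its mean of −0.69 in nhx5-2 lay at the no-target level of the arrays (−0.81 to −0.57), so the fall is a lower bound. AT2G32500 lay at that level in nhx5-2/nhx6-2 too but did not pass the test in nhx6-2 (0.01 ± 0.09) or in nhx5-1/nhx6-1 (−0.26 ± 0.09). The other named genes were AT5G24570 (−0.58 ± 0.08), the receptor-like kinase gene AT3G03770 (−0.44 ± 0.06), HYH, a light-signalling bZIP transcription factor gene (−0.42 ± 0.07), and AT1G64380, an ERF transcription factor gene that rose (0.32 ± 0.05).

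In total 15 probe sets changed in nhx5-2, 1 higher and 14 lower, and 1356 had an unadjusted p under 0.05. The arrays did not overlap for 13.6% of probe sets, against 10% by chance. No member of the 8 nuclear photosynthesis genes or the 69 chloroplast-encoded genes passed the test, also adjusted over the list alone. The camera test put the photosynthesis list lower, with a median of −0.26 (adjusted p 0.00151), and the chloroplast list higher, with a median of 0.12 (adjusted p 0.0339), in the line with the lowest 3′ minus 5′ signal; both had an adjusted p = 0.962 with an estimated correlation. The count was 3 without wild type replicate 1 or 3 or nhx5-2 replicate 1, 8 without nhx5-2 replicate 2 and 9 without nhx5-2 replicate 3. With the 3′ minus 5′ covariate it was 4, the median difference of the 15 going from 0.58 to 0.64 units and its standard error from 0.07 to 0.11. AT2G32500 kept its call each time, and the calls of the other 4 named genes ended with the covariate. The calls of AT5G24570 (adjusted p up to 0.0977) and AT3G03770 (up to 0.127) ended without wild type replicate 1 or 3 or nhx5-2 replicate 1, the former also without nhx5-2 replicate 3 and the latter without wild type replicate 2 or nhx5-2 replicate 2. Those of HYH (up to 0.237) and AT1G64380 (up to 0.222) ended without any 1 of the 6 arrays. The chloroplast list turned to a median of −0.11 without wild type replicate 2 and had an adjusted p of 0.949 without nhx5-2 replicate 2, and the photosynthesis list had one of 0.115 without wild type replicate 1. The chloroplast median also turned negative with the 3′ minus 5′ covariate, and the photosynthesis median turned positive with the cre covariate.

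**Figure D4:**
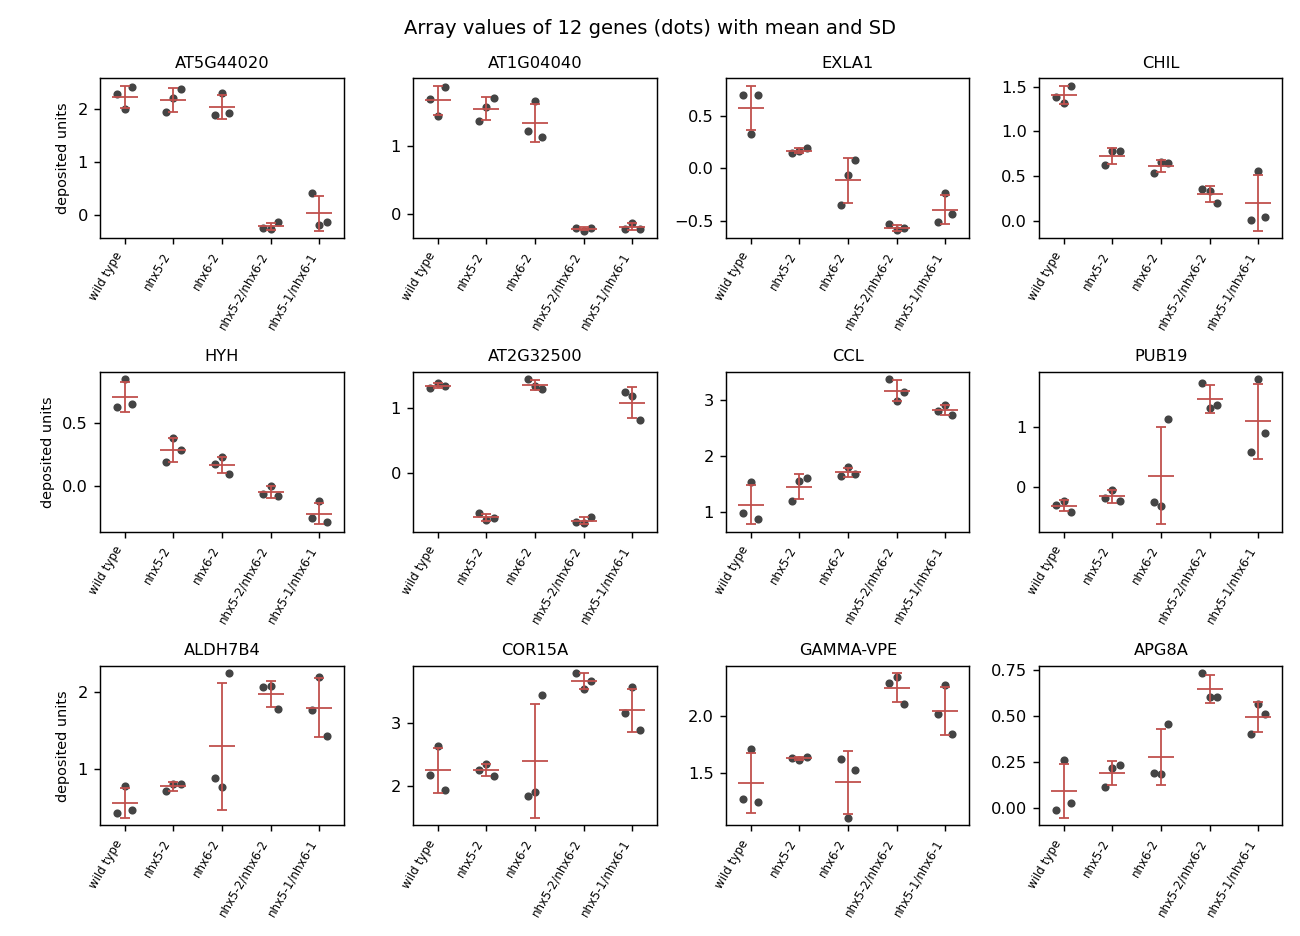
Values of 12 named genes on each of the 15 arrays, in deposited units, by genotype, with replicates 1, 2 and 3 from left to right in each genotype and the mean and SD (n = 3) in red. AT5G44020 and AT1G04040 are low in both double knockouts and near wild type in both single knockouts, and AT2G32500 is low in nhx5-2 and nhx5-2/nhx6-2.

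In the nhx6-2 single knockout AT1G06000, for a flavonol glycosyltransferase, differed from wild type by −0.88 ± 0.16 units (SE, n = 3), CHIL by −0.80 ± 0.12, AT2G44670 by −0.75 ± 0.14, the expansin-like gene EXLA1 by −0.69 ± 0.11 and AT3G56290 by −0.62 ± 0.11. Fes1B, for an exchange factor of heat shock chaperones, rose by 0.44 ± 0.06, AT1G64380 by 0.40 ± 0.05 and BIM1, a brassinosteroid signalling transcription factor gene, by 0.26 ± 0.04. The chaperone gene AT3G09440, one of the genes named for the double knockouts, also fell (−0.59 ± 0.11).

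In total 66 probe sets changed in nhx6-2, 6 higher and 60 lower, 29 of them with 1 gene, and 1531 had an unadjusted p under 0.05. For 13.99% of probe sets the arrays did not overlap, against 10% by chance. Of 11 autophagy genes and 3 auxin genes none passed the test, and 1 autophagy gene and no auxin gene rose when adjusted over the list alone. The lists had medians of 0.08 and 0.10 with adjusted p of 0.0012 and 0.0318, and adjusted p = 0.567 and 0.388 with an estimated correlation. None of the 69 chloroplast-encoded genes passed, also over the list alone, and their median of 0.18 gave an adjusted p of 9.08e-07, and an adjusted p = 0.803 with an estimated correlation, in a line whose 3′ minus 5′ signal lay below that of wild type. The count was 7 and 9 without wild type replicates 1 and 3 and 14 and 37 without nhx6-2 replicates 1 and 3. With the 3′ minus 5′ covariate it was 7, with none of the 8 genes named first among them; the median difference of the 66 went from 0.45 to 0.48 units and its standard error from 0.07 to 0.09. CHIL, EXLA1 and Fes1B lost their calls without wild type replicate 1 or 3 or nhx6-2 replicate 1 (adjusted p 0.056 to 0.135). AT1G06000 lost its call without any array but nhx6-2 replicate 3 (up to 0.185), and AT2G44670, AT3G56290 and BIM1 without any 1 of the 6 (up to 0.219, 0.229 and 0.179). The autophagy list had an adjusted p of 0.103 without wild type replicate 3, the auxin list 0.0896 and 0.154 without wild type replicate 2 and nhx6-2 replicate 2, and the chloroplast list a median of −0.05 without wild type replicate 2. The chloroplast median also turned negative with the 3′ minus 5′ covariate.

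Most probe sets called in a single knockout were also called in the double knockouts. AT5G24570 differed by −0.58, −0.54, −0.84 and −0.73 units in nhx5-2, nhx6-2, nhx5-2/nhx6-2 and nhx5-1/nhx6-1, HYH by −0.42, −0.54, −0.75 and −0.92, and AT3G03770 by −0.44, −0.36, −0.43 and −0.44. They were 3 of the 11 probe sets that were lower in all 4 knockouts, the other 8 having no single gene assigned. Of the 66 probe sets changed in nhx6-2, 63 changed the same way in nhx5-2/nhx6-2, where independent lists would share 0.256 higher and 3.32 lower, and 65 did in nhx5-1/nhx6-1. Of the 15 changed in nhx5-2, 14 changed the same way in nhx5-2/nhx6-2, 13 in nhx5-1/nhx6-1 and 12 in nhx6-2. Unchanged groups shared at most 0.05 probe sets on average in the simulations. Such groups yield hardly any calls, so this does not measure what the shared wild type arrays add. The covariance of nhx6-2 with nhx5-2/nhx6-2 was 0.0118 and that of nhx5-2 with nhx6-2 was 0.00592, against 0.00372 and 0.00375 simulated, with r = 0.56 and 0.57 against 0.50. For nhx5-2 with nhx5-2/nhx6-2 and nhx5-1/nhx6-1 the covariance was 0.00954 and 0.00908 against 0.00373 and 0.00373 simulated, while r was 0.47 and 0.44 and lay below the simulated 0.50. For nhx6-2 with nhx5-1/nhx6-1 they were 0.0112 and 0.52. Part of each excess may come from the shared wild type arrays.

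The 3′ minus 5′ signal was higher in nhx5-2/nhx6-2 than in each single knockout, and with it as a covariate 1 probe set was called against nhx5-2 and 9 against nhx6-2. The median differences of the probe sets called without it went from 0.41 to 0.31 and from 0.42 to 0.36 units and their standard errors from 0.09 to 0.16 and from 0.09 to 0.14. Against nhx5-2, 4 of 11 autophagy genes, 3 of 5 vacuolar proteases and 2 of 4 abscisic acid, drought and cold genes rose, with 8, 3 and 3 when adjusted over the list alone, and the lists had adjusted p of 2.10e-07, 0.0177 and 0.00251, and of 0.326, 0.326 and 0.415 with an estimated correlation. Against nhx6-2, whose replicate 3 had a mean of 1.96 units over the abscisic acid list against 0.777 and 0.817 on the others, the counts were 3, 2 and 2 with 7, 3 and 2 when adjusted over the list alone, and adjusted p of 6.93e-07, 0.00458 and 0.0153, and of 0.140, 0.140 and 0.477 with an estimated correlation. No fixed list had an adjusted p under 0.326 against nhx5-2 or under 0.140 against nhx6-2 with that setting. The folding list was higher in both (0 of 5 members past the test against nhx5-2 and 1 of 5 against nhx6-2, 2 of 5 over the list alone in each; adjusted p 0.0341 and 0.0195). The chloroplast-encoded list was lower in both, with medians of −0.16 and −0.24 (0 of 69 members against nhx5-2 and 1 of 69 lower against nhx6-2, 0 over the list alone; adjusted p 0.00391 and 6.05e-07). With the 3′ minus 5′ covariate both medians of this list turned positive. Other calls were the photosynthesis list higher against nhx5-2 (0.0341, with 1 of 8 members lower, and 3 higher and 1 lower over the list alone), and against nhx6-2 the auxin list lower (0.0327; 0 of 3, 2 lower alone), the cell wall loosening list lower (0.0357; 0 of 9, 1 lower alone) and the mitochondrion-encoded list higher (0.0283; 2 of 16 higher, 2 alone).

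In total 1239 probe sets changed between nhx5-2/nhx6-2 and nhx5-2, 628 higher and 611 lower, and 580 higher and 331 lower after shifting the arrays to one median. Without nhx5-2 replicate 1 the split was 328 higher and 602 lower, and without both arrays of low SD 816 and 1279. Against nhx6-2 there were 933, 449 higher and 484 lower, and 319 and 316 after the shift. The first count was 694 and 623 without nhx5-2 replicates 2 and 3, 359, 651 and 616 without the double knockout's replicates 1, 2 and 3, and 1 with the 3′ minus 5′ covariate. The second was 454 and 215 without nhx6-2 replicates 1 and 2, 193, 363 and 471 without the double knockout's replicates 1, 2 and 3, and 9 with that covariate. Single arrays ended list calls. Against nhx5-2, adjusted p was 0.0661 and 0.0614 for the vacuolar proteases without nhx5-2 replicates 2 and 3, and 0.125 and 0.440 for the chloroplast list without nhx5-2 replicate 2 and the double knockout's replicate 3. It was 0.0669, 0.113, 0.112 and 0.158 for the folding list without nhx5-2 replicates 1 and 2 and the double knockout's 1 and 2, and 0.271, 0.0614, 0.135 and 0.0675 for photosynthesis without replicates 1 and 3 of nhx5-2 and of the double knockout. Against nhx6-2 it was 0.0813 and 0.0525 for the abscisic acid list without nhx6-2 replicates 1 and 2, and 0.0692 for the folding list without the double knockout's replicate 2. It was 0.0525, 0.0585 and 0.0692 for the auxin list without nhx6-2 replicates 2 and 3 and the double knockout's 2, and 0.103, 0.0584 and 0.0942 for the cell wall list without nhx6-2 replicate 2 and the double knockout's 2 and 3. For the mitochondrial list it was 0.0780 and 0.0692 without replicate 2 of each.

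In nhx5-2/nhx6-2 a few genes departed from the sum of the single knockout differences, though no call held with the 3′ minus 5′ covariate. AT5G44020 lay −2.18 ± 0.23 units (SE) below that sum, with single knockout differences of −0.06 and −0.19 ± 0.16. AT3G16670 lay −1.59 ± 0.23 below it, AT1G04040 −1.44 ± 0.18, AT1G76240 −0.88 ± 0.15 and the vacuolar sugar transporter gene SWEET2 −0.61 ± 0.10. The glutaredoxin gene AT2G47880 lay 1.25 ± 0.20 above it, the drought-induced linker histone gene HIS1-3 0.85 ± 0.14, AT4G01390 0.84 ± 0.13 and the ERF family gene AT1G01250 0.75 ± 0.13. HIS1-3 lay at the no-target level in wild type and both single knockouts, where differences between them cannot be read.

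In total 22 probe sets had a non-additive effect, 10 higher and 12 lower, or 3 and 6 after shifting the arrays to one median and 186 and 132 after quantile normalization, and 2252 had an unadjusted p under 0.05. With the 3′ minus 5′ signal as a covariate 0 of the 22 calls held. Their median difference went from 0.81 to 0.65 units and its standard error from 0.13 to 0.27, with AT5G44020 at −1.98; the genotypes differed in that signal. The autophagy list (median 0.15, adjusted p 0.00389), the abscisic acid, drought and cold list (0.69, 0.0352) and the chloroplast-encoded list (−0.34, 5.01e-09) shifted with no member past the test; over the list alone 0, 2 and 0 members passed. On the abscisic acid list nhx6-2 replicate 3 stood apart, with a mean of 1.96 units against 0.777 and 0.817, and without it the median was 0.98. With the 3′ minus 5′ covariate each of these medians turned, to −0.0140, −0.0427 and 0.39. No fixed list had an adjusted p under 0.443 with an estimated correlation. Leaving out 1 array moved the count to between 2 and 8 for wild type replicates 1, 2 and 3 (3, 4 and 6), nhx5-2 replicates 2 and 3 (2 and 4), nhx6-2 replicates 1 and 2 (3 and 8) and the double knockout's replicates (3, 4 and 7), to 13 without nhx5-2 replicate 1 and to 148 without nhx6-2 replicate 3. AT5G44020 kept its call without each array. AT1G04040 lost it (adjusted p 0.0506 to 0.0589) without wild type replicate 1, nhx5-2 replicate 2 or 3 or the double knockout's replicate 1 or 2. AT3G16670 lost its call without any of 10 arrays (up to 0.099), and each of the other named genes without any of 11 arrays, with an adjusted p of up to 0.146. Without wild type replicate 2 the autophagy list had an adjusted p of 0.130 and the abscisic acid list 0.0700, and the latter had 0.0653, 0.0928, 0.139, 0.129 and 0.05004 without nhx5-2 replicates 1 and 3, nhx6-2 replicates 1 and 2 and the double knockout's replicate 3.

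Between the double knockouts, AT2G32500 was 1.83 ± 0.09 units higher in nhx5-1/nhx6-1 than in nhx5-2/nhx6-2 (SE, n = 3; adjusted p 3.04e-07), a lower bound since the latter lay at the no-target level. The lipid transfer protein family genes AT2G37870, AT3G53980 and AT4G33550 were lower. AT2G37870 differed by −1.24 ± 0.20, AT3G53980 by −1.18 ± 0.17, AT4G33550 by −0.84 ± 0.14 and the peroxidase gene AT5G51890 by −0.80 ± 0.08; AT5G51890 lay 0.45 above wild type in nhx5-2/nhx6-2 and −0.35 from it in nhx5-1/nhx6-1. The glycine-rich protein gene AT4G30460 differed by −0.80 ± 0.13. Higher in nhx5-1/nhx6-1 were psbA (1.06 ± 0.19), AT4G16870, a retrotransposon gene (0.82 ± 0.11), the beta tubulin gene TUB5 (0.48 ± 0.09) and iqd21 (0.48 ± 0.09).

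Of the 69 chloroplast-encoded genes 1 rose, with 17 higher when adjusted over the list alone, and their median of 0.38 gave an adjusted p of 7.10e-14, and an adjusted p = 0.472 with an estimated correlation; the 3′ minus 5′ signal was higher in nhx5-1/nhx6-1. None of the 16 mitochondrion-encoded genes passed, 5 were higher over the list alone, and the adjusted p was 0.00147, and 0.434 with an estimated correlation. None of the 8 nuclear photosynthesis genes passed, also over the list alone, and their median of −0.31 gave an adjusted p of 0.000718, and 0.434 with an estimated correlation. In total 86 probe sets differed, 28 higher and 58 lower in nhx5-1/nhx6-1, or 12 and 60 after shifting the arrays to one median. The split turned to 79 higher and 44 lower without nhx5-1/nhx6-1 replicate 3, and to 252 and 140 without both arrays of low SD. For 17.37% of probe sets the arrays did not overlap, against 10% by chance. The count was 6, 16 and 18 without nhx5-2/nhx6-2 replicates 1, 2 and 3, 44 and 345 without nhx5-1/nhx6-1 replicates 1 and 2, and 4 with the 3′ minus 5′ covariate. With it the median difference of the 86 went from 0.46 to 0.43 units and its standard error from 0.08 to 0.12. AT2G32500, AT3G53980, AT5G51890 and AT4G16870 kept their calls without each array. AT4G33550 lost its call without any nhx5-2/nhx6-2 array, AT2G37870, AT4G30460, iqd21 and TUB5 also without nhx5-1/nhx6-1 replicate 1, and psbA also without nhx5-1/nhx6-1 replicates 1 and 3 (adjusted p up to 0.204).

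Of the 6 measured among 25 proton pump genes and the 2 measured among 18 cation antiporter genes, CHX19 and CHX20, none changed in any of the 9 comparisons; adjusted over the list alone, 2 of the pumps' tests passed. CHX19 differed from wild type by 0.09 ± 0.05 and 0.08 ± 0.05 units in nhx5-2/nhx6-2 and nhx5-1/nhx6-1, and CHX20 by −0.01 ± 0.11 and 0.03 ± 0.11. The wild type mean of CHX19 lay within the range of the no-target medians over all arrays, though above those of the wild type arrays. Of the 2 measured among 37 trafficking genes, AT1G09330, which codes for the trans-Golgi protein ECHIDNA, fell in nhx5-1/nhx6-1 (−0.25 ± 0.07; adjusted p 0.0656, 0.0942, 0.0748 and 0.0835 without wild type replicates 1, 2 and 3 and mutant replicate 3) and ARA6 did not pass. Of 9 measured expansin and XTH genes, EXGT-A3 fell in nhx5-2/nhx6-2 (−0.67 ± 0.12) and nhx5-1/nhx6-1 (−0.58 ± 0.12) and 8 did not pass.

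Markers of other leaf cell types moved in part. Of 4 measured guard cell genes, AT1G22690 fell in nhx5-2/nhx6-2 (−0.98 ± 0.11) and nhx5-1/nhx6-1 (−0.46 ± 0.11, adjusted p 0.0807 without wild type replicate 3 and 0.0631 without mutant replicate 1), while SPCH, MUTE and FMA did not pass. The single trichome gene, TRY, a repressor of trichome fate, fell by 0.34 and 0.32 ± 0.07 units, in nhx5-1/nhx6-1 with an adjusted p of 0.0606 without wild type replicate 3. The vascular (GUT2), shoot meristem (CLV3) and root (EXPA7, EXPA18) genes passed in none of the 9 comparisons. MUTE and CLV3 lay at the no-target level in every genotype. On the wild type arrays SPCH and EXPA18 lay within the range of the no-target medians over all arrays, though above those of the wild type arrays.

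Of 512 genes written in the fixed lists 89 had a probe set assigned to them alone, and the hormone, defence and nutrient genes among these 89 changed in few cases. Others may lie among the probe sets that the annotation did not list, and nothing is said of them here. For salicylic acid, jasmonate and touch and wounding, 2 of 18, 2 of 22 and 2 of 18 genes were measured. These are too few to speak for the responses as a whole. On the wild type arrays PDF1.2 and the heat shock genes AT1G52560 and AT1G53540 lay within the range of the no-target medians over all arrays, PDF1.2 and AT1G53540 above those of the wild type arrays. SAG29, a sugar transporter gene of leaf senescence, rose in nhx5-2/nhx6-2 (0.79 ± 0.15) and did not pass in nhx5-1/nhx6-1 (0.33 ± 0.15). GI, a clock gene, rose in nhx5-1/nhx6-1 (0.33 ± 0.07). BHLH101 of the iron response also rose there (0.24 ± 0.06, with an adjusted p of 0.0667 and 0.0506 without wild type replicates 1 and 3). The BHLH101 difference may be a lower bound, as its wild type mean lay within the range of the no-target medians over all arrays. That mean lay above the no-target medians of the wild type arrays. BCAT4 of glucosinolate synthesis was higher by 0.87 ± 0.43 and 0.94 ± 0.43 in nhx5-2/nhx6-2 and nhx5-1/nhx6-1 without passing. No gene passed in any of the 9 comparisons among 2 salicylic acid genes (SAG101, GRX480), 2 jasmonate genes (PDF1.2, THI2.1), 2 touch and wound genes (WRKY53, STZ), 3 cell cycle genes, 4 anthocyanin genes and 6 heat shock genes. The adjusted p of the last 3 lists lay between 0.105 and 0.999, that of the proton pumps between 0.209 and 0.944 and that of the guard cell genes between 0.0517 and 0.961. Without nhx5-1/nhx6-1 replicate 3, the array with the lowest SD, the anthocyanin list passed in nhx5-1/nhx6-1 (median 0.59, adjusted p 0.000924), in the mean of both double knockouts (0.00921) and between them (0.00374). DFR (0.58, adjusted p 0.00559), AT4G14090 (0.60, 0.00206), UF3GT (0.62, 0.00269) and the jasmonate gene THI2.1 (0.48, 0.00471) then passed in nhx5-1/nhx6-1. The guard cell list passed for nhx5-2/nhx6-2 against nhx6-2 without nhx6-2 replicate 1 (0.0371) and without the double knockout's replicates 1 and 3 (0.0466 and 0.0446), and with the 3′ minus 5′ covariate (0.0232). The lists of potassium and sodium transport, phosphate starvation and flower genes had no member with a probe set assigned to it alone in the annotation, so they were not tested.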

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

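The tests of RNA integrity for nhx5-1/nhx6-1 and for nhx5-2/nhx6-2 against nhx6-2, of the arrays with a low SD, of the wild type arrays standing apart, of the loss of NHX5 function and of a change carried by the nhx5-2 line were chosen after the result was seen. A tested difference between the double knockouts singled out 11 named genes. In nhx5-1/nhx6-1 minus nhx5-2/nhx6-2, AT2G32500 differed by at least 1.83 units, psbA by 1.06, AT4G16870 by 0.82, TUB5 by 0.48, iqd21 by 0.48 and BIM1 by 0.31, and AT2G37870 by −1.24, AT3G53980 by −1.18, AT4G33550 by −0.84, AT5G51890 by −0.80 and AT4G30460 by −0.80. A tested difference between the effect of losing NHX6 with and without NHX5 singled out 10 genes: AT5G44020 at −2.18, AT3G16670 at −1.59, AT1G04040 at −1.44, AT1G76240 at −0.88, SWEET2 at −0.61, AT1G64380 at −0.56, AT2G47880 at 1.25, HIS1-3 at 0.85 (from the no-target level in 3 of the 4 genotypes), AT4G01390 at 0.84 and AT1G01250 at 0.75.

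The double knockouts changed many more probe sets than the single knockouts. RNA integrity was argued against as the whole source of the calls in nhx5-2/nhx6-2 against wild type, whose signals overlapped. There 1571 probe sets were called with the 3′ minus 5′ signal as a covariate, 1532 of them among the 2232. With it 7 were called in nhx6-2, but this count is no fair comparison. The nhx6-2 signal (1.55 to 1.69) lay wholly below that of wild type (1.79 to 1.97). Whether RNA integrity adds to the gap between double and single knockouts stays open. Neither array with a low SD belongs to nhx5-2/nhx6-2 or wild type, so leaving them out acts there only through the pooled spread. Without them 3916 probe sets were called in nhx5-2/nhx6-2, 396 in nhx6-2 and 15 in nhx5-2. A gap therefore remained, though the nhx6-2 count rose from 66. Wild type arrays standing apart would have set the single knockouts apart as well, with 15 and 66 called. They would also have left little between nhx5-2/nhx6-2 and nhx6-2, with 933 called (193 without the double knockout's replicate 1). Both points concern the gap only. Of the single knockout calls 14 of 15 and 60 of 66 were falls and 12 were shared, so for these calls wild type arrays standing apart stay open as a source. With the covariate 24 probe sets were called in nhx5-1/nhx6-1 and 9 in nhx5-2/nhx6-2 against nhx6-2, the standard error rising from 0.08 to 0.15 and from 0.09 to 0.14 units and the median difference going from 0.36 to 0.31 and from 0.42 to 0.36; in both, RNA integrity and genotype cannot be told apart, because the signals of the groups did not overlap. The joint loss of both antiporters stays open as a biological explanation.

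AT2G32500 was low in the lines with the nhx5-2 allele. Loss of NHX5 function was argued against by nhx5-1/nhx6-1, which lay at least 1.83 units above nhx5-2/nhx6-2, if its NHX5 was lost as labelled. A change carried by the nhx5-2 line stayed open: nhx5-2 and nhx5-2/nhx6-2 differed by −0.0549 units, but both lay at the no-target level, where the floor fixes how alike they are. A lesion spanning several genes stayed open, as the number of measured genes within 5 genes on either side that fell by over 0.5 units was 0, of 1 measured, which differed by 0.13. Whether the nhx5-2 line holds a second insertion or another variant there was not tested.

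Probe sets lower in nhx6-2 were also lower in nhx5-2/nhx6-2. The shared wild type arrays were argued against as the whole source. Over the 60 probe sets lower in nhx6-2, the median of nhx5-2/nhx6-2 minus nhx5-2 was −0.32 units, with 56 of them below 0. It was −0.34 to −0.28 without 1 nhx5-2 or nhx5-2/nhx6-2 array, and −0.23 with the 3′ minus 5′ covariate (median SE 0.14). The wild type and nhx6-2 arrays, which chose the 60 probe sets, were not left out in turn. The same probe sets had a median of −0.34 in nhx5-2 minus wild type, where NHX6 was intact, and of −0.23 in nhx5-2/nhx6-2 minus nhx6-2, with 51 below 0. The former uses the wild type arrays, and the latter the nhx6-2 arrays, that chose the 60 probe sets. That choice alone pulls the former below 0, so it is no separate support for an effect of losing NHX5. The effects of losing NHX6 and of losing NHX5 both stay open as biological explanations.

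With 3 arrays against 3 there are 10 splits, too few for a share under 0.05, and in each comparison only 1 split, the real one, reached its count. The real and the highest other counts were 15 and 0 for nhx5-2, 66 and 0 for nhx6-2, 2232 and 1 for nhx5-2/nhx6-2, 2736 and 0 for nhx5-1/nhx6-1, 86 and 36 between the double knockouts, and 1239 and 0 and 933 and 0 for nhx5-2/nhx6-2 against nhx5-2 and nhx6-2. For the mean of both double knockouts 1 of 100 splits reached the count of 3024, the highest other being 2579. For the probe sets changed in both 1 of 100 reached 1467, the highest other being 1320. Both others kept the wild type arrays together and only mixed the double knockouts. Splits that broke up the wild type arrays reached at most 687 and 31. Mixing real groups also widens the spread within them, which lowers such counts. A random grouping was therefore argued against as the source, but not excluded. For the non-additive effect 2 of 100 splits reached the count of 22. Splits of all 12 arrays also break up the genotypes' own effects, so they do not test the non-additive part alone, and whether those 22 calls came from a random grouping stays open. The highest other, 301, put all nhx5-2/nhx6-2 arrays in the place of wild type and all wild type arrays in the place of nhx6-2. Its contrast therefore contained the real difference between nhx5-2/nhx6-2 and wild type, for which 2232 probe sets were called.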

How the results depend on the processing

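The omission of both arrays with a low SD and the cre and 3′ minus 5′ covariates were chosen after the results were seen. The alternative with other pseudocounts was not run, because the deposited values were already on a log-like scale. Unless a reason is given, the cause of a move was not tested. Of 123 calls of named genes, quantile normalization ended 1, a variance prior with trend 5, the omission of both low-SD arrays 5, arrays shifted to one median 15, the cre covariate 20, only the arrays compared 31 and the 3′ minus 5′ covariate 73. Of 39 list calls, the variance prior and the mean of all probe sets of a gene ended 0, arrays shifted to one median 3, array weights 7 and quantile normalization 10. No count moved by over 1.5 times under the variance prior, and those that moved under other settings follow. The no-target probe sets had array medians of −0.81 to −0.57, and transcripts near that level carry little signal over background.

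Quantile normalization gave 33 probe sets for nhx5-2, 247 for nhx6-2, 379 between the double knockouts, 2248 and 1725 for nhx5-2/nhx6-2 against nhx5-2 and nhx6-2, and 318 for the non-additive effect. Arrays shifted to one median gave 34 for nhx6-2 and 9 for the non-additive effect, and leaving out dim probe sets gave 132 between the double knockouts. With only the arrays compared the counts were 8 for nhx5-2, 4379 for nhx5-2/nhx6-2, 1149 for nhx5-1/nhx6-1, 5 between them, 1931 and 1438 against nhx5-2 and nhx6-2, and 254 for the non-additive effect. Array weights gave 1074 for nhx5-2, 1454 for nhx6-2, 7169 for nhx5-2/nhx6-2, 6955 for nhx5-1/nhx6-1, 8078 for their mean, 2751 between them, 5116 and 4487 against nhx5-2 and nhx6-2, 2665 for the non-additive effect and 4361 for both; weights lay between 0.0856 and 3.25.

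With only probe sets of 1 gene, which tests fewer by construction, the counts were 3 for nhx5-2, 28 for nhx6-2, 1118 for nhx5-2/nhx6-2, 1371 for nhx5-1/nhx6-1, 1535 for their mean, 45 between them, 616 and 405 against nhx5-2 and nhx6-2, 6 for the non-additive effect and 718 for both. With a difference of at least 1 unit, which is stricter by construction, they were 1, 1, 120, 95, 104, 5, 58, 54, 8 and 64 in the same order.

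Without both arrays of low SD the counts were 396 for nhx6-2, 3916 for nhx5-2/nhx6-2, 4634 for the mean, 392 between the double knockouts, 2095 and 2399 against nhx5-2 and nhx6-2, 200 for the non-additive effect and 2262 for both. The cre covariate gave 3 for nhx5-2, 1718 for nhx5-1/nhx6-1 and 5 for the non-additive effect. The 3′ minus 5′ covariate gave 4 for nhx5-2, 7 for nhx6-2, 24 for nhx5-1/nhx6-1, 429 for the mean, 4 between the double knockouts, 1 and 9 against nhx5-2 and nhx6-2, 0 for the non-additive effect and 21 for both, while nhx5-2/nhx6-2 had 1571, 1532 of them among the 2232. For nhx5-2/nhx6-2 against nhx5-2 the median difference went from 0.41 to 0.31 units and its standard error from 0.09 to 0.16, as the groups differed in that signal.

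The replicate numbers did not pair the arrays: of 30 same-numbered pairs 6 correlated above 0.1 and 18 below 0, and 2 of 15 arrays were closest to their own number. With the replicate number as a block the counts were 11 for nhx5-2, 47 for nhx6-2, 2055, 2528 and 2817 for the double knockouts and their mean, 26 between them, 1055 and 732 against the single knockouts, 6 for the non-additive effect and 1363 for both.

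Leaving out 1 array at a time gave 3 to 15 for nhx5-2, 7 to 54 for nhx6-2, 1165 to 2090 for nhx5-2/nhx6-2, 1479 to 2872 for nhx5-1/nhx6-1, 1596 to 3765 for their mean, 6 to 345 between them, 359 to 930 and 193 to 1246 against nhx5-2 and nhx6-2, 2 to 148 for the non-additive effect and 767 to 1770 for both. List calls numbered 39 in the main analysis, 35 to 41 without 1 array, gained calls included, and 0 with an estimated correlation.

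Directions turned in few cases. EXPA7 in nhx5-1/nhx6-1 differed by −0.12 with array weights. Without wild type replicate 2 the chloroplast list had medians of −0.11 in nhx5-2, −0.0459 in nhx6-2 and −0.16 for the mean of both double knockouts, and over all omissions of 1 array it ranged from −0.11 to 0.25 in nhx5-2 and from −0.0459 to 0.33 in nhx6-2. With the cre covariate the photosynthesis list had medians of 0.0382 in nhx5-2, 0.24 in nhx5-2/nhx6-2 and 0.15 against nhx6-2. With the 3′ minus 5′ covariate the chloroplast list had −0.29 in nhx5-2, −0.0589 in nhx6-2, 0.32 and 0.0914 against nhx5-2 and nhx6-2 and 0.39 for the non-additive effect, where the autophagy list had −0.0140 and the abscisic acid list −0.0427.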

Other observations

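All lists in this paragraph were formed after the results were seen. The tubulin genes TUB5 (−0.43 ± 0.09) and TUB7 (−0.42 ± 0.09) fell in nhx5-2/nhx6-2, and TUB7 (−0.43 ± 0.09) and TUA1 (−0.32 ± 0.07) in nhx5-1/nhx6-1. Of 7 measured tubulins, 2 fell and 5 did not pass in each double knockout, with 5 and 2 lower when adjusted over the list alone. The list had an adjusted p of 0.00331 in nhx5-2/nhx6-2 (adjusted p = 0.411 with an estimated correlation) and 0.0767 in nhx5-1/nhx6-1, and 3 fell against each single knockout (0.000609 and 4.37e-07, with p = 0.326 and 0.140 with an estimated correlation). Of 9 dehydration proteins 1 rose in nhx5-2/nhx6-2 and 2 rose in nhx5-1/nhx6-1, with 4 and 3 when adjusted over the list alone, and an adjusted p of 0.0110 (p = 0.512 with an estimated correlation) and 0.0536. Of 9 U-box ubiquitin ligases 1 and 2 rose (adjusted p 0.815 and 0.0767). Of 20 beta-glucosidases 1 rose and 1 fell in nhx5-2/nhx6-2 and 3 rose in nhx5-1/nhx6-1 (0.815 and 0.555), with BGLU25 higher by 0.75 and 0.62 ± 0.08 units and BGLU44 by 0.78 in nhx5-1/nhx6-1.

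Families without a shift as a whole held single changes. EXPA16, an expansin gene, rose (1.00 and 0.56 ± 0.14 in nhx5-2/nhx6-2 and nhx5-1/nhx6-1), while the wall acetylation gene TBL45 (−1.07 and −0.82 ± 0.12), the secretory pathway gene PRA1.B6 (−0.53 and −0.61 ± 0.08), GSTU27 (−0.56 and −0.60), UGT74D1 (−0.55 and −0.55), scpl48 (−0.32 and −0.49) and the tetraspanin gene TET10 (−0.48 and −0.27) fell. VPS20.1 of the endosomal sorting machinery rose (0.30 and 0.34). Of 42 cell wall genes 4 rose and 3 fell in nhx5-2/nhx6-2 and 3 rose and 4 fell in nhx5-1/nhx6-1. The numbers in the same order were 0, 3, 1 and 2 of 22 TBL genes, 1, 1, 0 and 2 of 14 SWEET genes, 2, 5, 4 and 4 of 47 UGT genes, 0, 2, 1 and 2 of 11 GSTU genes, 2, 3, 2 and 3 of 37 carboxypeptidase and subtilase genes, 4, 1, 2 and 1 of 32 tether and sorting genes and 0, 1, 0 and 1 of 15 tetraspanins. None of these lists passed in any of the 9 comparisons, with adjusted p between 0.102 and 0.989.

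On nhx6-2 replicate 3 the mean of the 4 abscisic acid, drought and cold genes was 1.96 units, against 0.777 and 0.817 on nhx6-2 replicates 1 and 2. It was 0.897, 1.31 and 0.811 on the wild type arrays 1 to 3, 0.952, 1.07 and 0.886 on the nhx5-2 arrays, 1.92, 1.74 and 1.89 on the nhx5-2/nhx6-2 arrays and 1.71, 2.19 and 1.54 on the nhx5-1/nhx6-1 arrays. Across probe sets, the deviation of nhx6-2 replicate 3 from the other nhx6-2 arrays correlated with nhx5-2/nhx6-2 minus nhx5-2 at r = 0.44, against −0.50 and −0.09 for replicates 2 and 1. Wild type replicates 1, 2 and 3 gave −0.24, 0.36 and −0.34 against the same difference, so such a shift was not particular to nhx6-2. Each deviation is taken from the other arrays of its genotype, so the values within a genotype are not independent.

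It was asked whether insertions changed the transcripts of genes beside NHX5 and NHX6. Of 14 measured genes within 10 genes on either side, 9 beside NHX5 and 5 beside NHX6, 0 were called in the single knockout of the disrupted gene. Their median absolute difference was 0.09 units against 0.04 for all probe sets with 1 gene, so the question stays open. AT1G54410, beside NHX5, was higher by 0.56 units in nhx5-2/nhx6-2 (adjusted p 0.00832). It was also asked whether the effect of losing NHX6 was alike with and without NHX5. Across probe sets, nhx5-2/nhx6-2 minus nhx5-2 correlated with nhx6-2 minus wild type, which shares no array with it, at r = 0.31. The following checks were added after this value was seen. Without nhx6-2 replicate 3 the r was 0.0698, and without any other array it was 0.21 to 0.46. With only the deviations of the wild type and nhx6-2 arrays from their group means in place of nhx6-2 minus wild type, r ran from −0.52 to 0.52, and 5 of 18 splits reached 0.31. The question therefore stays open.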
